A study of Homo sapiens with 9 samples.

How the data were processed

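Polyadenylated RNA was sequenced from SKOV3 cells, an established human ovarian carcinoma line, in 3 groups of 3 libraries: control cells, cells given placental micro-sized extracellular vesicles (micro-EVs) and cells given placental nano-sized extracellular vesicles (nano-EVs). Per the labels' protocols, cells were grown in DMEM with fetal bovine serum and given 200 ug of placental vesicles for 24 h, RNA was taken with Magzol and selected with oligo-dT, and libraries were made with a NEBNext Ultra RNA kit. The same treatment text stood on the control libraries, so what the control cells received was not given in the sources used here. Each title carried a number from 1 to 3, shared between the groups, and no label said what the number marks. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

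The authors deposited a table of 38637 genes with the whole-number count of each library, unnormalized per the file header and the values. The same deposited table gave a TPM column per library and a gene length column. The deposited TPM values equalled the count divided by the deposited length and scaled to a fixed total per library, with a largest difference of 1.7e-05%, so TPM carried no further information and was not tested. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.2 and the hg38 build, with no role or order. The strand setting and the treatment of overlapping genes were not given in the sources used here. BEST1, which overlaps FTH1, held 37.1 to 44.4 counts per 100 FTH1 counts in every library, so reads in overlapping genes seem to have entered both rows, and overlapping or antisense genes were read as uncertain. Near-identical gene families (histones, metallothioneins, CGB, CSH and GH, PSG, CCL3 and its copies) were likewise read as uncertain gene by gene. Gene coordinates are those of the deposited table and cover the whole annotated gene, with exons and introns.

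Counts were tested as deposited, in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, which left 16754 genes holding at least 99.9% of the counts of each library, and 10154 genes had no count anywhere. Libraries were scaled by TMM factors, and all 9 entered 1 model of group means, fitted with glmQLFit with robust estimation and tested with glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM, the counts-per-million values of edgeR, on TMM-scaled library sizes, with the standard deviation (SD) over libraries, except that summed levels of marker and liver lists, and the levels and floors of APOA1 and CGA, used the plain library totals. The comparisons were micro-EVs against control, nano-EVs against control, nano-EVs against micro-EVs, and the mean of both vesicle groups against control. A floor of 3 counts stood for a count of 0, and the floors and exact 95% intervals cover counting error only.

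Before the data were examined, 30 pathway lists and 5 cell type marker lists were fixed, and 926 of their 939 symbols had a row. The 13 absent symbols were the mitochondrially encoded genes, so that list was not tested, and GBA1 was found under its older symbol GBA. Pathway and marker lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list's genes moved more than other genes, and fry whether they moved, on balance, one way.

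The genes named in the text followed a rule fixed at the same time. For each comparison it took up to 8 genes per direction with the largest log2 fold change among called genes with a mean of at least 5 CPM, no overlap between libraries of the groups and an approved-style symbol. It added up to 2 called members of each list with the smallest p, always ERBB2, MUC16, MKI67 and CGA, and, where fewer than 5 genes were called in a direction, the 5 with the smallest p at 5 CPM or more, given as values. List members given as examples without a call, HK2, SMAD7, RN7SK and the genes named for the contrast between number 3 and numbers 1 and 2 were chosen after their values were seen.

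The libraries numbered 3 differed from the others in every group, so all comparisons were repeated on the 6 libraries numbered 1 and 2, with 16989 genes kept. This alternative, a term for number 3, the fit without ribosomal RNA genes, DESeq2 with the replicate block and the leave-one-out fits with the block were chosen after seeing the data. The replicate numbers were checked as pairs before the fits were compared. Deviations from the group mean, correlated across genes, reached 0.38 to 0.77 between libraries of the same number, above the 0.1 fixed for pairing in every pair. Libraries numbered 1 and 2 also deviated together, at 0.24 to 0.60, and number 3 against any other number gave -0.39 at most. Control 2 deviated more with micro-EV 1 and nano-EV 1 (0.58 and 0.60) than with micro-EV 2 and nano-EV 2 (0.43 and 0.38). Control 1 also went more with number 1 (0.48 and 0.50) than with number 2 (0.29 and 0.24). Within numbers 1 and 2 the number was thus not shown to pair the controls with their vesicle libraries. The pairing therefore comes from the data and not from the labels, and it mainly parts number 3 from numbers 1 and 2. The fit with the number as a block is given where it changed a call.

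The alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors, library size alone, a looser and a stricter count filter, DESeq2 1.42.0, limma voom, fits of only the groups compared, the replicate block, stricter thresholds and leaving out each library. No pair of libraries agreed within sampling noise, so each library counted as 1 sample. Chi-square per degree of freedom over genes was at least 6.42 between any pair and 18.2 within a group. The closest pair was micro-EV 2 with nano-EV 2, followed by micro-EV 3 with nano-EV 3 (8.31) and control 2 with micro-EV 1 (9.41).

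The procedure was tested on simulated counts drawn for the comparison of micro-EVs with control, with known changes. Without a block, edgeR on 16490 simulated genes recovered 0% of the genes changed 1.5-fold, 17.9% of those changed 2-fold and 69.7% of those changed 4-fold. DESeq2 without a block, on 16754 genes, recovered 2.99%, 55.2% and 92.4%, and limma voom 0%, 16.4% and 66.7%, each of the 3 tests with 0 false calls. With the replicate block the edgeR shares were 49.3%, 91% and 100%, with 9 false calls. On the 6 libraries numbered 1 and 2, with 16509 simulated genes, they were 10.4%, 64.2% and 97%, with 1 false call, and 32.8%, 88.1% and 98.5% with the block, with 18 false calls.

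Total counts ranged from 18667582 to 28350071 per library. Genes of the Y chromosome, XIST and TSIX were left out of every reported list and figure.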

Results

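RNA sequencing measured transcript levels in SKOV3 cells, a human ovarian carcinoma line with high ERBB2, after exposure to extracellular vesicles from placenta. Vesicles of 2 size classes were used, micro-EVs and nano-EVs, with control cells as the third group and 3 libraries in each. In the order of the numbers 1 to 3 in their titles, the control libraries held 23767095, 21258445 and 21990733 counts. The micro-EV libraries held 18667582, 28350071 and 22137965 counts, and the nano-EV libraries 22100007, 27112281 and 18966533. Genes with at least 1 count numbered 20904 to 23375 per library. Ribosomal RNA genes took 1.37% to 4.35% of the counts. ERBB2, the receptor tyrosine kinase amplified in this line, stood at 3300 ± 715 CPM in control, 3550 ± 172 in micro-EV and 3460 ± 184 in nano-EV libraries (SD, n = 3).

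The libraries numbered 3 differed from those numbered 1 and 2 in every group, and by more than the groups differed from each other. CRYAB, a small heat shock protein, averaged 50.9 CPM in the 3 libraries numbered 3 and 1.87 in the other 6 (log2 difference 4.78 ± 0.14 SE). The matrix metalloproteinase MMP7 averaged 52.7 against 5.11 CPM. TXNIP and DDIT4, which respond to glucose and stress, were higher in number 3 by log2 1.98 ± 0.10 and 1.75 ± 0.10. The growth factor EREG averaged 0.846 against 9.54 CPM, the cytokine IL1A 4.30 against 23.9 CPM and the long non-coding RNA NEAT1 46.7 against 231 CPM. The proliferation marker MKI67 was lower in number 3 (515 against 991 CPM), and ID1, an inhibitor of helix-loop-helix transcription factors, was higher (1290 against 326 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4186 genes were higher and 4625 lower in number 3, of 16754 tested.

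**Figure D1:**
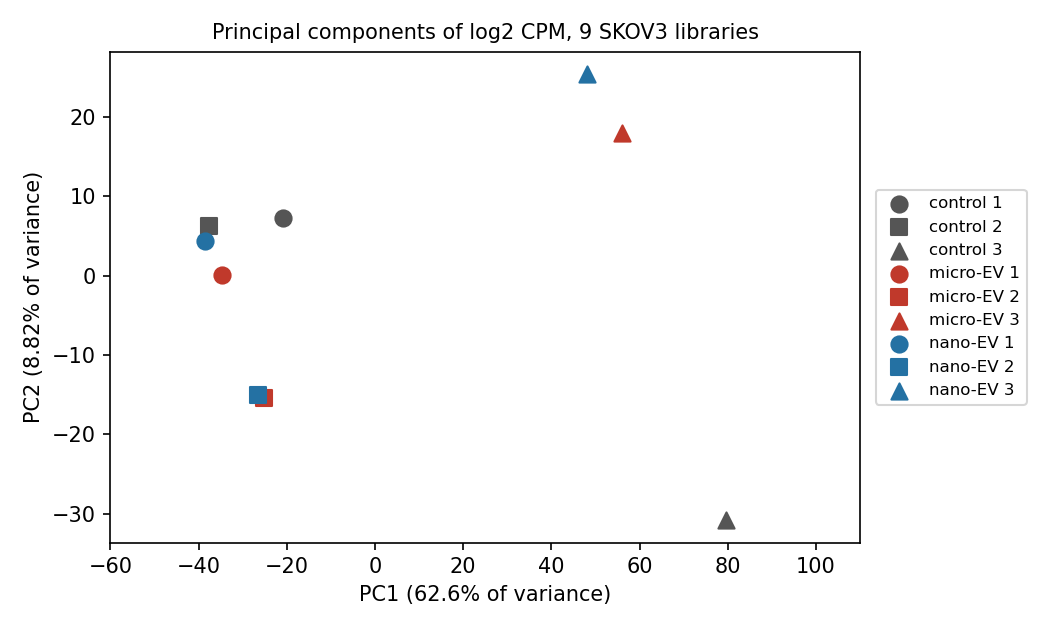
Principal components of log2 CPM over the tested genes, with PC1 (62.6% of the variance) on the x axis and PC2 (8.82%) on the y axis, and 1 point per library. The 3 libraries numbered 3 lie at 48.1 to 79.5 on PC1 and the other 6 at -38.5 to -20.9, whatever their group.

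The comparison of micro-EV with control libraries addressed the first question of the design, which mRNA levels differ in the cancer cells after placental vesicles. Replication-dependent histone transcripts, which encode the proteins that package new DNA, fell as a list. Of 23 members, 22 lay below control, with a median log2 fold change of -0.66 (camera adjusted p = 5.25e-21, adjusted p = 0.413 with an estimated correlation). Single members stood at -0.80 ± 0.37 (SE) for H3C10 and -0.63 ± 0.26 for H2AC6, and near-identical histone genes can share reads. The mean log2 CPM of the list was close to control in number 1 (0.76 in micro-EV 1, 0.81 in control 1) and farthest from it in number 2 (-0.24 in micro-EV 2, 1.35 in control 2). The number was not shown to pair control 1 and 2 with these libraries, and both micro-EV 1 and micro-EV 2 lay below control 2. The list median was -0.45 without micro-EV 2. Micro-EV 2, with the lowest histone level, also had the lowest share of ribosomal RNA genes (1.37% against 3.78% in control 2). Targets of TGF-beta and SMAD signalling fell as a list, with 20 of 21 members lower and a median of -0.21 (adjusted p = 0.00568, adjusted p = 0.624 with an estimated correlation). Targets of YAP and TEAD, the factors of the Hippo pathway, also fell, with 18 of 21 lower and a median of -0.13 (adjusted p = 0.00301, adjusted p = 0.841 with an estimated correlation). Among them were CRIM1 at -0.53 ± 0.31 and ANKRD1 at -1.52 ± 0.99. None of these members passed the test by itself, over all genes or adjusted over the list alone. Replicate block fits added the list of epithelial to mesenchymal transition (median -0.14, camera adjusted p = 0.0235, adjusted p = 0.734 with an estimated correlation). Lists called numbered 0 with an estimated correlation and 0 with fry.

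Among single genes, the smallest p-values on the higher side belonged to DEPTOR, an mTOR-binding inhibitor, PPP1R1A, an inhibitor of protein phosphatase 1, C16orf91, the carbonic anhydrase CA2 and KAZN. DEPTOR (chromosome 8, 119873722 to 120050918, hg38) averaged 10.1 ± 2.36 CPM in micro-EV and 4.78 ± 1.09 CPM in control libraries (SD, n = 3), a log2 fold change of 1.09 ± 0.29 (SE). PPP1R1A averaged 9.87 ± 3.27 against 3.09 ± 1.52 CPM (SD, n = 3). On the lower side stood PTGES, the inducible prostaglandin E synthase, with CCDC80, SYTL3, the serotonin receptor HTR1D and TIAM2. PTGES (chromosome 9, 129738349 to 129753042) averaged 3.92 ± 0.261 against 9.35 ± 2.51 CPM (SD, n = 3), a log2 fold change of -1.26 ± 0.27 (SE). ERBB2 (0.10 ± 0.17 SE), the CA-125 antigen gene MUC16 (0.38 ± 0.53) and MKI67 (0.05 ± 0.37) differed by less than their errors or by about 1 error. By edgeR's quasi-likelihood test, 0 of 16754 genes were called (adjusted p = 1 for each gene named here), with 116 genes at an unadjusted p under 0.05. DESeq2 and limma voom also called 0, and so did edgeR with the replicate block, where the smallest adjusted p was 0.0886. DESeq2 with the replicate block, chosen after seeing the data, called 50 genes, 33 of them with a mean under 1 CPM.

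Within the 6 libraries numbered 1 and 2, a choice made after seeing the data, 36 genes differed between micro-EVs and control, 12 higher and 24 lower. The 4 inhibitors of DNA binding, which block helix-loop-helix transcription factors and are classic targets of BMP signalling, were among the genes that fell. ID3 was 9.99-fold lower (log2 -3.32 ± 0.24 SE, adjusted p = 1.19e-05) and ID4 5.66-fold (-2.50 ± 0.22, adjusted p = 2.52e-06). ID2 was 5.65-fold lower (-2.50 ± 0.20, adjusted p = 4.21e-07) and ID1 4.13-fold (-2.05 ± 0.15, adjusted p = 8.52e-08). ID1 (chromosome 20, 31605289 to 31606510) stood at 530 and 446 CPM in control 1 and 2 and at 132 and 103 CPM in micro-EV 1 and 2. ID2 lies on chromosome 2 (8682056 to 8684461), ID3 on chromosome 1 (23557926 to 23559501) and ID4 on chromosome 6 (19837370 to 19842197). SMAD6, an inhibitory SMAD, fell 2.08-fold (adjusted p = 5.1e-04), the Wnt antagonist DKK1 1.94-fold (adjusted p = 0.001) and PTGES 2.80-fold (adjusted p = 8.25e-04). The long non-coding RNA UCA1 fell 2.51-fold (adjusted p = 4.8e-05) and the antiangiogenic matrix protein THBS1 (chromosome 15, 39581079 to 39599466) 1.78-fold (adjusted p = 0.0124). ZNF114, the sterol desaturase SC5D and the polyamine acetyltransferase SAT1 fell by 1.13, 0.74 and 0.70 on the log2 scale. PPP1R1A rose 4.47-fold (adjusted p = 0.0103), the cytokine signalling inhibitor CISH 2.26-fold (adjusted p = 0.00225) and DEPTOR 2.14-fold (adjusted p = 0.0259). The cross-linking enzyme TGM2 rose 2.07-fold (adjusted p = 2.68e-04) and the angiogenic factor VEGFA (chromosome 6, 43770209 to 43786487) 1.55-fold (adjusted p = 0.0389). SIGLEC15, ANGPTL4, ARHGAP22 and C1QTNF6 rose by log2 1.07 ± 0.18, 0.95 ± 0.16, 0.90 ± 0.18 and 0.75 ± 0.14 (SE). In number 3 these genes lay on the other side, at log2 -0.76, -0.64, -0.20 and -0.09 in micro-EV 3 against control 3.

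With the replicate block on the same 6 libraries, 11 of these 36 genes were called by edgeR and no others, 2 higher and 9 lower. ID1 to ID4 (adjusted p = 3.56e-04 for ID1), UCA1, SMAD6, DKK1, PTGES, TGM2 and CISH were among them. VEGFA, THBS1, DEPTOR and PPP1R1A were not (adjusted p = 0.112, 0.112, 0.0864 and 0.0864). The TGF-beta and SMAD list, which holds ID1 to ID3, SMAD6 and TGM2, had 18 of 21 members lower here (camera adjusted p = 6.24e-22, adjusted p = 0.0507 with an estimated correlation). Of these, 1 was called higher and 4 lower over all genes, and 1 and 6 adjusted over the list alone. A separate list of TGF-beta and SMAD2/3 targets, chosen after seeing the data, had 12 of 20 members lower here. Its median was -0.04 (camera p = 0.185 with an estimated correlation), so the lower level was not shown for those targets. Interferon gamma and antigen presentation genes (17 of 21 higher, median 0.23, adjusted p = 0.00323) and NF-kB and inflammatory cytokine genes (19 of 25 higher, median 0.14, adjusted p = 9.81e-04) rose as lists here. With an estimated correlation their adjusted p was 0.953 and 0.825. In micro-EV 3 the ID genes lay near control 3, with ID1 at 1300 against 1460 CPM and ID3 at 404 against 502 CPM. The change of ID1 differed between number 3 and numbers 1 and 2 by log2 1.88 ± 0.26 (SE, interaction test, adjusted p = 0.00119), where the single libraries numbered 3 are taken to vary like the others. Such a difference was also called for ID2, ID3 and ID4 (adjusted p = 2.37e-04, 0.0221 and 0.00119).

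**Figure D2:**
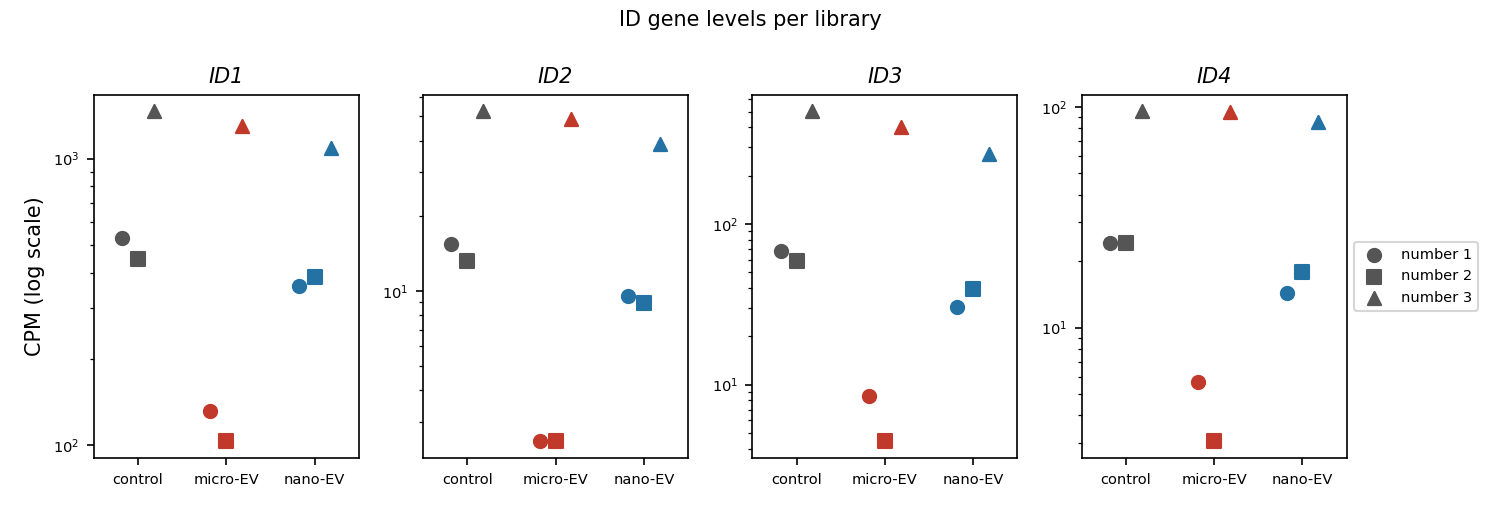
Levels of ID1 to ID4 in CPM, on a log axis, with 1 point per library, groups along the x axis and the number in the title as the symbol. In numbers 1 and 2 the micro-EV libraries lie lowest for each gene (ID1 132 and 103 CPM), while the 3 libraries numbered 3 lie between 1090 and 1460 CPM for ID1.

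**Figure D3:**
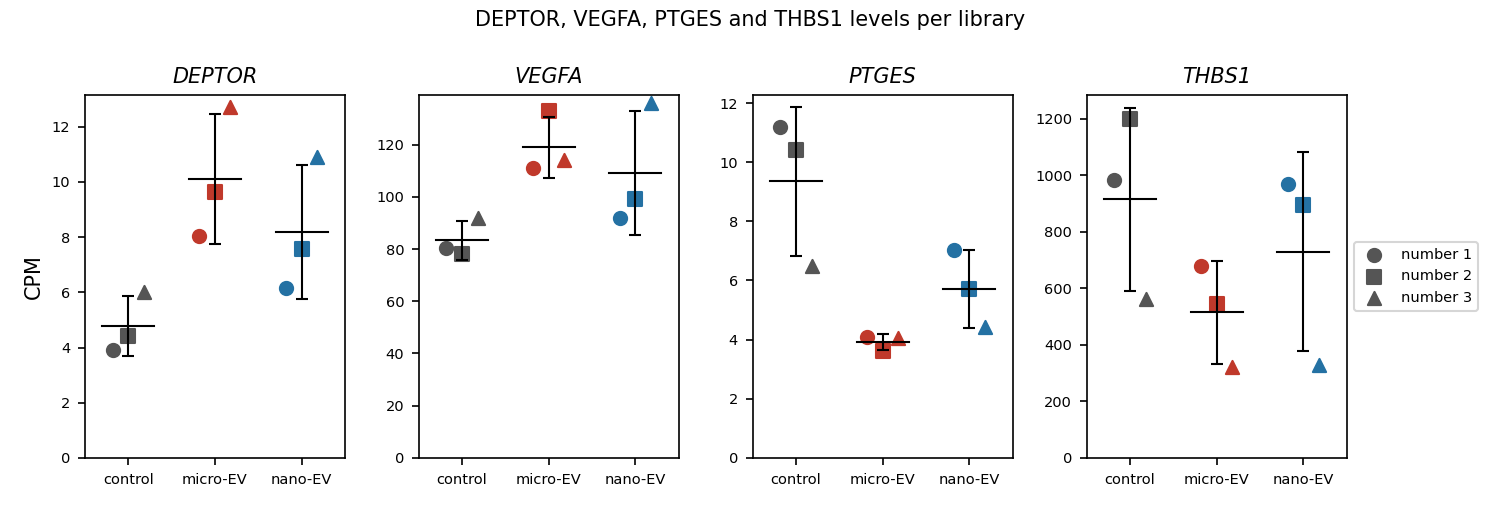
Levels of DEPTOR, VEGFA, PTGES and THBS1 in CPM from 0, with 1 point per library, a bar at the mean of 3 libraries and whiskers of 1 SD. DEPTOR is higher in the vesicle library than in the control of the same number in all 3 numbers for micro-EVs (8.04, 9.64 and 12.7 against 3.92, 4.40 and 6 CPM), and THBS1 in number 3 lies below 600 CPM in every group.

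The comparison of nano-EV with control libraries asked the same question of the smaller vesicles. Histone transcripts fell as a list here too, with 22 of 23 members lower and a median of -0.57 (camera adjusted p = 1.53e-14, adjusted p = 0.633 with an estimated correlation). H3C10 stood at -1.17 ± 0.38 (SE) and H2AC6 at -0.71 ± 0.26. Without control 2 the list median was -0.33, and over genes with a mean of at least 1 CPM it was -0.25. Nano-EV 2 held 45.2 CPM of histone transcripts in sum and the lowest ribosomal RNA share of its group (1.6%). In number 3 the mean log2 CPM of the list was close to control (0.68 in nano-EV 3, 0.72 in control 3). Genes of hypoxia and glycolysis rose as a list by a small median of 0.08, with 22 of 33 members higher (adjusted p = 0.0478, adjusted p = 0.633 with an estimated correlation). HK2, the enzyme that starts glycolysis, stood at 0.62 ± 0.29 and VEGFA at 0.39 ± 0.17. Lysosome and autophagy genes fell as a list, with 24 of 33 lower and a median of -0.15 (adjusted p = 0.0205, adjusted p = 0.861 with an estimated correlation), including GRN at -0.35 ± 0.32 and the acid glucosidase GAA at -0.23 ± 0.27. Without control 3 the median of that list turned to 0.06. Members called over all genes or adjusted over the list alone numbered 0.

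The replicate block raised the number of lists called from 3 to 7. It added TGF-beta and SMAD targets (18 of 21 lower, median -0.18, adjusted p = 0.00303) and epithelial to mesenchymal transition genes (median -0.06, adjusted p = 0.0158), with an adjusted p = 0.559 and 0.587 with an estimated correlation. It also added immediate early genes on the lower side (median -0.06, adjusted p = 0.0271) and cell cycle genes on the higher side (36 of 50 higher, median 0.09, adjusted p = 0.0164). With an estimated correlation their adjusted p was 0.751 and 0.728. DEPTOR stood at 8.20 ± 2.43 CPM (SD, n = 3) against 4.78 ± 1.09 in control, a log2 fold change of 0.78 ± 0.29 (SE). It was followed on the higher side by the small GTPase RALA (0.39 ± 0.14), the nucleolar protein gene NOP16 (0.49 ± 0.19), the Ras activator RASGRP1 (0.57 ± 0.22) and CCNA1 (0.46 ± 0.18). The triglyceride lipase PNPLA2 (-0.44 ± 0.14), the transcription factors KLF2 (-0.69 ± 0.23) and NKX6-2 (-0.57 ± 0.19), SYTL3 (-0.47 ± 0.16) and CITED2 (-0.47 ± 0.16) led the lower side. ERBB2 (0.07 ± 0.17), MUC16 (-0.01 ± 0.53) and MKI67 (0.17 ± 0.37) lay within their errors of 0. By edgeR's quasi-likelihood test 0 genes were called (adjusted p = 1 for each), with 114 at an unadjusted p under 0.05. DESeq2, limma voom, edgeR with the replicate block and edgeR on numbers 1 and 2 called 0 as well, and DESeq2 with the block called 37 genes, 32 of them with a mean under 1 CPM. On numbers 1 and 2, ID1 to ID4 stood at log2 -0.39, -0.62, -0.86 and -0.58 (adjusted p = 0.952, 0.833, 0.729 and 0.952).

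Nano-EV libraries were compared with micro-EV libraries directly, which tests whether the vesicle classes differ in effect. Cholesterol synthesis and uptake genes were higher with nano-EVs as a list, with 20 of 25 members higher and a median of 0.10 (camera adjusted p = 0.0176, adjusted p = 0.762 with an estimated correlation). HMGCS1 stood at 0.16 ± 0.17 (SE) and the LDL receptor LDLR at 0.09 ± 0.12. Lists of type I interferon response (25 of 32 lower, median -0.10, adjusted p = 0.0233), interferon gamma and antigen presentation (17 of 21 lower, median -0.09, adjusted p = 0.0176) and NF-kB and inflammatory cytokines (20 of 25 lower, median -0.10, adjusted p = 0.0283) were lower. With an estimated correlation these 3 lists also had an adjusted p = 0.762. Examples were the antiviral OAS1 at -0.41 ± 0.34, the guanylate-binding GBP1 at -0.33 ± 0.21 and TNFAIP3, an NF-kB feedback inhibitor, at -0.33 ± 0.16. Of these 4 lists, 0 members were called over all genes or adjusted over the list alone. The replicate block added hypoxia and glycolysis on the higher side (25 of 33 higher, median 0.07, adjusted p = 0.0396, adjusted p = 0.664 with an estimated correlation).

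Within numbers 1 and 2, ID1 to ID4 were higher with nano-EVs than with micro-EVs, by log2 1.66 ± 0.15 (SE), 1.87 ± 0.20, 2.46 ± 0.24 and 1.92 ± 0.22 (adjusted p = 3.4e-06, 8.08e-05, 4.16e-04 and 2.13e-04). UCA1 was higher by 1.12 ± 0.15 (adjusted p = 9.34e-04). These, with LOC105377845, an uncharacterized gene named after its values were seen, were the 6 genes called there, and 5 of the 6 were called with the replicate block. The TGF-beta and SMAD list was higher there (15 of 21 higher, median 0.05, camera adjusted p = 1.31e-13, adjusted p = 0.102 with an estimated correlation), with 3 members called higher. Over all 9 libraries 0 genes were called by edgeR's quasi-likelihood test (adjusted p = 1 for each gene named), with 44 at an unadjusted p under 0.05. DESeq2, limma voom and edgeR with the replicate block called 0, and DESeq2 with the block 29 genes, 27 of them with a mean under 1 CPM. RPPH1, the RNA of ribonuclease P, and PARP2, a DNA repair enzyme gene, led the higher side at 3.55 ± 1.11 and 0.78 ± 0.33 through 1 library: nano-EV 1 held 62 CPM of RPPH1 and 93.7 CPM of PARP2. RPPH1 (chromosome 14, 20343071 to 20343411) lies within PARP2 (20343041 to 20357904), and its reads can count for both. CCDC80 (0.34 ± 0.15), DMPK (0.37 ± 0.17) and COL8A1 (0.32 ± 0.15) followed. FAM102A (-0.50 ± 0.22), GPC6 (-0.38 ± 0.17), PPIL6 (-0.43 ± 0.20), APOL6 (-0.25 ± 0.12) and CREG2 (-0.38 ± 0.18) led the lower side. ERBB2 (-0.04 ± 0.17), MUC16 (-0.38 ± 0.53) and MKI67 (0.12 ± 0.37) were within about 1 error of 0.

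Averaging the vesicle groups against control, 0 genes were called by edgeR's quasi-likelihood test, with 137 at an unadjusted p under 0.05. DESeq2, limma voom and edgeR with the replicate block called 0, and DESeq2 with the block 39 genes. Without control 2, the liver-type genes AGT and APOA1, named after their values were seen, were called. With a term for number 3 the non-coding RNA RN7SK was the 1 gene called, on the lower side. In numbers 1 to 3 it stood at 8.59, 20.7 and 37.9 CPM in control libraries. Micro-EV libraries held 3.78, 2.13 and 15.1 CPM and nano-EV libraries 4.1, 4.16 and 19.2 CPM. Carry-over of RNA without a poly(A) tail was not tested for this gene. On numbers 1 and 2, 18 genes were called, 4 higher and 14 lower, and 11 with the replicate block, 1 higher and 10 lower. DEPTOR was on the higher side and SYTL3 on the lower side among the smallest p-values of both vesicle comparisons. The log2 fold changes of the vesicle comparisons correlated across genes at 0.64, with genes not being independent replicates, and 75.9% of genes had the same sign. Unchanged groups simulated with a shared control group gave 0.51 (0.49 to 0.53 in 10 simulations) and 66.9%. The covariance was 0.049 against a simulated 0.032 (0.030 to 0.034). Simulated libraries varied independently around a mean for each number. In the data, chi-square per degree of freedom between micro-EV and nano-EV libraries was 11.3, 6.42 and 8.31 in numbers 1 to 3. Between control and micro-EV libraries of the same number it was 16.8, 44.5 and 33.7, but 9.41 between control 2 and micro-EV 1. The simulation lacked such closeness between single libraries, so the higher observed values cannot be read as a shared vesicle effect. By edgeR no gene was called in both comparisons (0 in the simulations, 0 for independent lists), against 19 by DESeq2 with the block. Part of that overlap may come from the shared controls, which are too few to be split.

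Transcripts of placental and blood cells were measured to see whether the vesicle libraries held RNA of those kinds. The trophoblast list summed to 607 to 726 CPM over the 9 libraries, led in each by SDC1, a proteoglycan also made by epithelial cells. It did not pass the test with micro-EVs (median 0.06, camera adjusted p = 0.379) or nano-EVs (median -0.11, adjusted p = 0.94). CSH1, a placental lactogen gene, had 1 count in all, and CSH2 and GH2 had 0. CGA, the alpha subunit of chorionic gonadotropin, fell under the count filter, with 7 counts in micro-EV 1, 20 in micro-EV 2 and 0 in the other 7 libraries. Erythroid markers summed to 0.0841 to 0.706 CPM. Leukocyte and macrophage markers summed to 25.2 to 35.8 CPM, mostly CD68, endothelial markers to 44.1 to 61.8 CPM, led by EGFL7, and fibroblast and decidual stroma markers to 38.0 to 96.4 CPM, led by COL1A1. Endothelial markers (camera adjusted p = 0.885 and 0.81 with micro-EVs and nano-EVs) and stromal markers (adjusted p = 0.971 and 0.614) did not pass the test, and the erythroid and leukocyte lists had too few tested members. For each of these 4 lists the control range overlapped the vesicle range. A list of liver-secreted proteins, chosen after seeing the data, stood higher with micro-EVs (16 of 21 members higher, median 1.02, camera p = 1.02e-12, p = 0.0698 with an estimated correlation) and with nano-EVs (20 of 21 higher, median 0.90, p = 2.34e-17, p = 0.0384 with an estimated correlation). With the replicate block, p with an estimated correlation was 0.223 and 0.171. On the 6 libraries numbered 1 and 2 its medians were -0.14 with micro-EVs and 0.12 with nano-EVs. APOA1, an apolipoprotein of that list, stood at 0.0421, 5.50 and 0 CPM in control 1, 2 and 3 and at 3.08 to 6.64 CPM in the vesicle libraries.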

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

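Every test of a difference between number 3 and the other numbers, and every test of an explanation given here, was chosen after the result was seen; the counts over other splits of the samples were planned. No group was large enough for a test of single outlying libraries.

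The change with vesicles differed between number 3 and numbers 1 and 2, by an interaction test, for 7 genes in the micro-EV comparison, for 24 in the nano-EV comparison and for 4 in nano-EVs against micro-EVs. In the micro-EV comparison the change in number 3 minus that in numbers 1 and 2 was 2.41 on the log2 scale for ID2, 1.88 for ID1, 2.51 for ID4, 3.02 for ID3 and 4.98 for A2M. The 24 genes of the nano-EV comparison all had the higher change in number 3 (adjusted p = 0.0488 to 0.0494), and were not tested for a shared function. Among them the chaperone HSP90AA1 stood at 554 CPM in control 3 against 2700 and 2180 in control 1 and 2. Control 3 enters both vesicle comparisons, and the difference of HSP90AA1 with micro-EVs was 1.27 (adjusted p = 0.0924). The 4 genes of the last comparison were ID1 to ID4. A2M, a plasma protein made in liver, held 89 and 117 counts in micro-EV 3 and nano-EV 3 and 3 to 25 in the other libraries. Each of these tests rests on 1 library per group in number 3.

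ID1 to ID4 were lower in micro-EV 1 and 2 than in the controls of the same numbers, by a mean of log2 -2.59, and not in micro-EV 3. Labels exchanged among the libraries numbered 3 were argued against, since none of these lay below another by more than log2 -0.48 on average over the 4 genes. An exposure without effect in the culture of micro-EV 3 cannot be told apart from a response that depends on the state of the cells. The 32 other called genes kept a median of 13% of their change there (quartiles 0.653% to 45.4%). Of these, 25 had the same direction in number 3, and DEPTOR kept 97.2% and THBS1 97.9%. TGM2 kept 2.31%, and SIGLEC15, ANGPTL4, ARHGAP22, C1QTNF6 and SC5D were among the genes that turned. Lower output of the BMP and SMAD1/5 pathway in micro-EV 1 and 2 also stayed undecided, as the other 17 targets had a median of -0.10 (quartiles -0.42 to 0.14, p = 0.0843 with an estimated correlation), and without SMAD6 and ATOH8, known to be called beforehand, -0.05 (p = 0.421). A difference in vesicle dose or preparation between the numbers was not tested.

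The histone list was lower with both vesicle classes over all libraries, but not evenly. Its mean log2 CPM was 0.76 in micro-EV 1 against 0.81 in control 1, and 0.68 in nano-EV 3 against 0.72 in control 3. The gap was widest in number 2, where control 2 had the highest level of all libraries (1.35). The number was not shown to pair control 1 and 2 with their vesicle libraries. With these controls set the other way, micro-EV 1 stood at 0.76 against 1.35 and micro-EV 2 at -0.24 against 0.81. Fewer cells in S phase were argued against: polyadenylated S phase transcripts had a median change of 0.01 with micro-EVs and 0.09 with nano-EVs. Carry-over of RNA without a poly(A) tail cannot be told apart from a lower histone level, since a covariate for 12 other such transcripts left 68.9% of the mean change with micro-EVs and 95.1% with nano-EVs. Micro-EV 2 and nano-EV 2 held the lowest sums, at 38.5 and 45.2 CPM, and the lowest ribosomal RNA shares, while micro-EV 1 at 72.3 CPM lay within the range of the controls, 67.5 to 81.4 CPM.

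In genes under the count filter, 3 had at least 25 counts in the vesicle libraries and 0 in the controls. CCL3, a macrophage chemokine, had 88 counts, 44 each in micro-EV 2 and nano-EV 2, and its near-identical copy CCL3L3 had 131, 63 and 68 in the same 2 libraries. CGA had 27 counts, in micro-EV 1 and 2. Pooled over the micro-EV libraries, this was at least 8.72-fold above a floor of 3 counts over the control libraries. All of these genes were chosen for a count of 0 in the controls, so a level above that floor follows from the choice. Genes with counts in the controls alone were not sought.

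The numbers of genes and lists called were set against other splits of the libraries. In each comparison of 2 groups all 10 of the 10 splits called as many genes as the real one, which called 0, as did the highest other; 10 splits are too few for a share under 0.05. For lists the real split called 3, 3 and 4 in the micro-EV, nano-EV and direct comparisons, and the highest other split 10, 9 and 10. As many were called by 10, 8 and 6 of the 10 splits, the real one included. These shares lay above the 0.05 set beforehand, so the numbers of lists called did not stand out from those of other splits. Among the 3 other splits that part all 3 pairs of numbers, which mix the groups but not the numbers, the highest called 10, 6 and 4 lists. For the averaged comparison the real split called 0 genes, so all 84 of 84 splits called as many by construction, which says nothing about chance; the same holds for the gene counts of the other comparisons. The split that sets the 3 libraries numbered 3 against the rest called 9158 genes, which points to a structure of the samples along the numbers, and the fit with the replicate block called 0.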

How the results depend on the processing

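The fits on numbers 1 and 2, with a term for number 3, without ribosomal RNA genes, by DESeq2 with the block and leaving out libraries with the block were chosen after seeing the data. No gene was called over all 9 libraries under any other scaling, filter, tool or threshold set beforehand, nor with the replicate block (0 in each comparison). Leaving out a library gave 0 to 2 genes in the averaged comparison, with 2 without control 2, and 0 in the others. With the block it gave 0 to 13 genes with micro-EVs (13 without control 2 or micro-EV 3, 5 without control 3, 3 without nano-EV 3, 2 without micro-EV 1) and 0 to 17 with nano-EVs (17 without control 2, 2 without micro-EV 2). Between the vesicles it gave 0 to 6 (6 without micro-EV 3, 2 without control 2), averaged 0 to 25 (25 without control 2, 14 without micro-EV 3, 4 without micro-EV 1, 2 without micro-EV 2) and 0 to 11 in both vesicle comparisons. DESeq2 with the block called 50, 37, 29 and, averaged, 39 genes, 19 in both, with 33, 32 and 27 of the first 3 counts under 1 CPM. A term for number 3 gave 1 gene in the averaged comparison. Numbers 1 and 2 gave 36, 0, 6 and 18 genes, and with the block 11, 0, 5 and 11. With the block, 12 of the 13 genes called without micro-EV 3 were among the 36, and 1 of the 13 called without control 2. The cause of these differences was not tested. The self-test recovered more genes with the block, but its counts were drawn around means set by the number, which favours the block. Depth was not varied, so the self-test does not tell what set the counts of 0.

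Lists called with micro-EVs ranged from 2 (without micro-EV 2) to 9 (without control 3), with 5 on numbers 1 and 2. With nano-EVs they ranged from 2 (without micro-EV 2 or 3) to 6 (without control 3, nano-EV 2 or nano-EV 3), with 6 at a mean of 1 CPM or more and 7 with the replicate block. Between the vesicles they ranged from 2 (without nano-EV 1) to 8 (without micro-EV 1). An estimated correlation and fry called 0 lists in all 3 comparisons, with all 9 libraries or the block; on numbers 1 and 2 they called 0 except fry with micro-EVs, which called 1. Beside the lists named in the report, the block changed no call.

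Over libraries left out, medians crossed 0 for lysosome (-0.25 to 0.06) and cell cycle genes (-0.09 to 0.20) with nano-EVs, and for hypoxia genes (-0.06 to 0.15) between the vesicles, where cholesterol genes (0.02 to 0.16) kept a positive median but turned in camera's direction without nano-EV 3; immediate early genes with nano-EVs turned to 0.03 on numbers 1 and 2. Among named genes the log2 fold change of ERBB2 ranged from -0.06 to 0.25 with micro-EVs and -0.10 to 0.21 with nano-EVs, that of MUC16 from -0.03 to 1.00, -0.27 to 0.61 and, between the vesicles, -0.73 to 0.03, and that of MKI67 from -0.26 to 0.29, -0.14 to 0.41 and -0.11 to 0.33. MKI67 with micro-EVs was -0.02 on numbers 1 and 2, and MUC16 with nano-EVs was 0.02 by library size alone, 0.12 by voom and 0.05 with the block. None of these was called. Of 775 values of named genes 753 kept direction and call, 5 gained a call and 17 turned; of 240 list medians 165 kept both, 49 lost a call, 21 gained one and 5 turned. Marker sums without their leading gene moved in 13 of 15 cases. Library size alone shifted the median of all genes by 0.039 and 0.034 on the log2 scale with micro-EVs and nano-EVs, and TMM by -0.003 and -0.002.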

Other observations

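The tests of the lists for liver, macrophage and placental transcripts, of number 3 against numbers 1 and 2, and of the liver traces were chosen after the results were seen.

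Gene lists were compared between the 3 libraries numbered 3 and the other 6, over all groups together. Nuclear oxidative phosphorylation genes were higher in number 3, with 25 of 36 called higher and 0 lower (median log2 0.36, camera adjusted p = 1.2e-05). With an estimated correlation its adjusted p was 0.5, as for every other list here but the ribosomal one (adjusted p = 0.632), so that no list was called. By camera, cytosolic ribosomal protein genes were also higher, with 33 of 58 called higher and 1 lower (median 0.33, adjusted p = 1.2e-05), and lysosome and autophagy genes, with 22 of 33 higher and 1 lower (median 0.33, adjusted p = 7.71e-05). Interferon gamma and antigen presentation genes had 14 of 21 called higher and 2 lower (median 0.75, adjusted p = 0.00168). TGF-beta and SMAD targets had 13 of 21 higher and 4 lower (median 0.76, adjusted p = 0.0251), and cholesterol genes 12 of 25 higher and 1 lower (median 0.29, adjusted p = 0.0251). YAP and TEAD targets had 0 of 21 called higher and 17 lower (median -0.57, adjusted p = 4.68e-04), and cell cycle genes 5 of 50 higher and 31 lower (median -0.45, adjusted p = 7.64e-04).

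Of 30 listed transcripts of liver-secreted proteins, the 15 scarce ones summed to 2.69 CPM in control 1 and 1.64 in control 3, and to 41.3 in control 2, 24.5, 26.9 and 48.1 in the micro-EV and 31.5, 30.4 and 52.5 in the nano-EV libraries. The profiles of the 7 libraries other than control 1 and 3 differed by more than counting error, with a chi-square per degree of freedom of 15. Of 1000 sets of 15 other genes with matched counts, 4 reached this value (median 4.74, a test chosen after the profiles were seen). The 15 transcripts were picked for under 10 counts in their lowest library and at least 60 in all, and the sets were not. The rank is therefore not like for like and does not decide whether these libraries shared a single source. RNA that came with the vesicles, the one explanation tied to the groups, stayed open. However, control 2 lay above micro-EV 1 and 2 and nano-EV 1 and 2, at 1.68 times the level of the lowest vesicle library. By the rule used, written after the values were seen, 1 high control could not reject this explanation. Reads that entered in runs shared by pairs of libraries cannot be told apart from RNA that came with the vesicles, since no label names a run. The 3 closest pairs (micro-EV 2 with nano-EV 2, micro-EV 3 with nano-EV 3, control 2 with nano-EV 1) agreed to a chi-square per degree of freedom of 2.7 or less.

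A list of abundant placental transcripts was lower with nano-EVs than with micro-EVs, with 9 of 11 tested members lower and a median of -0.24 (camera p = 0.00431, p = 0.0327 with an estimated correlation, fry p = 0.162). Abundant macrophage transcripts were higher with micro-EVs than in control, with 7 of 8 members higher and a median of 0.21 (camera p = 0.0196, p = 0.0523 with an estimated correlation, fry p = 0.0189). Other RNAs without a poly(A) tail had a median of -0.18 with micro-EVs (camera p = 0.00384, p = 0.104 with an estimated correlation) and 0.19 with nano-EVs (camera p = 0.906). Within numbers 1 and 2, lists tried beside the BMP targets had medians of -0.04 for SMAD2/3 targets, -0.07 for glucocorticoid and progesterone receptor targets, -0.06 for retinoic acid targets and 0.25 for PPAR targets with micro-EVs (p = 0.185, 0.364, 0.32 and 0.0941 with an estimated correlation). These p-values were not adjusted.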
